A study of Schizosaccharomyces pombe with 17 samples.

How the data were processed

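The series holds 17 samples of fission yeast, Schizosaccharomyces pombe, in 5 genotypes. PolyA-selected RNA was sequenced from 14 libraries in 7 groups of 2, and RNA with an adapter ligated to its 3′ ends was sequenced from 3 libraries, 1 per genotype. Per the labels, RNA was isolated with a commercial yeast kit, the polyA libraries were made with a dUTP kit that keeps the strand, and sequencing was paired-end Illumina. Wild type, rrp6Δ and rrp6-cat were grown in rich YES medium at 32 °C to mid-log phase. The temperature-sensitive strains dis3-4 and rrp6-cat dis3-4 were grown at 23 °C and then moved to 30 °C for 1 h, and both temperatures were sampled. Each genotype is a separately named strain in the labels, and whether the strains share a parent is not given in the sources used here.

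The submitters' processing notes name TopHat2 2.1.0, Bowtie2 without a version, Cufflinks 2.2.1, Cuffnorm and Cuffdiff, with genome build ASM294v2. The authors deposited FPKM (fragments scaled to transcript length and to the mapped fragments of a library) for 7027 features in each of the 14 polyA libraries, made with Cuffnorm per the submitters' processing notes. The gene annotation, the way Cuffnorm scaled the libraries, the use of strand in counting and the numbers of reads are not given in the sources used here. A separate deposited table gives FPKM from Cuffdiff for 5 conditions with replicates combined. Its wild type column equals 0.934 times wild type replicate 1 with a weight of 0.000 for replicate 2, while its other columns are weighted sums of both replicates, so it was not used for any test. For the 3′-ligated libraries the authors deposited signal as read coverage at positions of chromosome III (3 files, whole numbers, tool and scaling not given in the sources used here). That coverage levels off, with maxima of 9014, 8993 and 8996, and is taken as capped there.

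Features were matched by systematic ID to the reference table, which paired 6854 of them, 4423 with a gene symbol. The reference at hand is build ASM294v3, so every coordinate printed is one of the deposited files, and the reference served only for gene names, chromosomes, lengths, neighbours and overlaps of genes, and searches for similar sequence. The deposited FPKM tables hold no coordinates. FPKM were used as deposited, with 1 added before taking log2. Genes with a mean of at least 1 FPKM over the 14 libraries were tested, which left 6083. The log2(FPKM + 1) scale understates fold changes of genes with low FPKM. The files hold very small values, with 244 features above 0 and under 1e-10 FPKM in some library, and these were treated like 0. An FPKM of 0 can be a failed estimate: the essential genes psm3, cct5 and rpt5 lie under 0.1 FPKM in 11, 14 and 11 of the 14 libraries. Depth is known only in relative terms, from the smallest steps between low FPKM values, which put wild type replicate 2 at 0.24 times the depth of wild type replicate 1.

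All 14 libraries entered 1 linear model of 7 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and an intensity trend. From it 10 comparisons were taken, each with limma's two-sided moderated test and Benjamini-Hochberg adjustment over the 6083 genes, and a gene was called at an adjusted p under 0.05. A group of 2 libraries leaves 1 residual degree of freedom, so the spread is shared across groups. Wild type varied most between replicates (mean square of log2 values 0.663, and 0.166 to 0.334 in the other groups). The shared spread therefore understates the error against wild type, and p-values there can be too small. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples only. The groups, the comparisons, the alternatives, the rule for named genes and 24 gene lists were fixed before the data were examined. The 22 lists with enough measured members were tested with camera at a preset correlation of 0.01, adjusted over 220 tests, and beside it with an estimated correlation and with fry. Measured members are those that passed the filter, and counts and shares of a list are over these only. They were 11 of 13 genes for the Mmi1 list, 7 of 15 for recombination and 11 of 18 for middle meiosis. They were 39 of 53 snoRNAs, 31 of 196 tRNAs and 17 of 49 rRNA features. The filter used all 14 libraries, so a gene near 0 in wild type passed only where mutant libraries held it. Of 72 camera calls, 1 held with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, called 46 of them. Called members of a list were also counted with the adjustment over the list alone.

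The rule for named genes took rrp6 and dis3, the 8 largest rises and the 6 largest falls among called genes that reached 5 FPKM in the higher group with both libraries of one group above both of the other, and up to 4 members with the largest change of each list with a called member. For the 3′-ligated libraries it took the 5 positions with the largest values and the 5 with the largest differences. Genes outside this rule are marked in the text as chosen after their values were seen.

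At each position of 3′ coverage, exact Poisson intervals (95%) were set side by side, ratios of 2 counts carry intervals on the log scale, and the share of 1 count in a sum of 2 carries an exact Clopper-Pearson interval. These intervals cover counting error only, since reads copied by PCR are not independent molecules, and 1 library per genotype allows no test between genotypes. The positions singled out in that coverage were chosen after it was seen. A position that a file does not list was taken as a coverage of 0. Coverage of 8000 or more was taken as the plateau, and a position needed a coverage of at least 10 in some library.

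The method was tested on simulated data. With 200 changed genes of 6083 in each of 10 draws, the test of rrp6Δ against wild type found 16.8%, 74.6%, 93.0% and 95.4% of genes changed by 1, 2, 3 and 4 log2 units, and 5.2% of its calls were unchanged genes. The test of the temperature shift in dis3-4 found 15.2%, 73.4%, 91.8% and 95.8%, with 5.0% unchanged genes among its calls. The simulation gave each gene the same spread in all groups, while wild type varied most in the data. The rates for rrp6Δ against wild type therefore do not cover that wider spread. Camera called a raised list of 20 genes in 10 of 10 draws and an unchanged one in 0. The simulated genes were independent of each other, so this does not test camera on lists whose genes move together. In a comparison simulated without change, 1 gene was called over all draws. With equal simulated 3′ coverage at most 0 positions were called, and with coverage raised by a factor of 4 at least 173 of 173 were. The simulated wild type coverage was the mean of the 3 observed libraries, which is above the observed wild type. Library totals were taken as equal and positions as independent. These counts therefore do not cover unequal totals, a wild type coverage as low as observed, or reads shared between positions.

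The alternatives tried were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5 FPKM, median-of-ratios size factors, quantile normalization, a fit of the compared groups alone, no intensity trend, a further requirement of 1 log2 unit, replicate number as a block, and each library left out in turn. For the 3′ coverage they were a stricter minimum of 100, no minimum, a share of summed coverage, and narrower and wider windows. Effects that share the wild type libraries were compared with 100 simulations of unchanged groups set against the same controls. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the 3′ coverage, the tables and the plots, and BLAST 2.17.0 for sequence searches.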

Results

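Abundance of polyA-selected RNA was measured as FPKM in 14 libraries from wild type fission yeast and from mutants of the exonucleases of the nuclear RNA exosome, Rrp6 and Dis3. The 7 groups of 2 libraries were wild type, rrp6Δ and rrp6-cat at 32 °C, and dis3-4 and the double mutant rrp6-cat dis3-4, each at 23 °C and after 1 h at 30 °C. Every group mean below is of 2 libraries, with its SD. Read totals are not given in the sources used here. The FPKM of a library summed to between 618712 in wild type replicate 2 and 842245 in rrp6-cat replicate 2. Wild type replicate 2 also had the fewest genes at 1 FPKM or more, 5619, where the other libraries had 5849 to 6017, and the lowest correlation with its replicate, 0.929 across genes. Wild type replicate 1 correlated more with rrp6-cat replicate 1, at 0.954, than with wild type replicate 2. Wild type was sampled at 32 °C only, so for the dis3-4 strains genotype and temperature differ together against wild type.

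**Figure D1:**
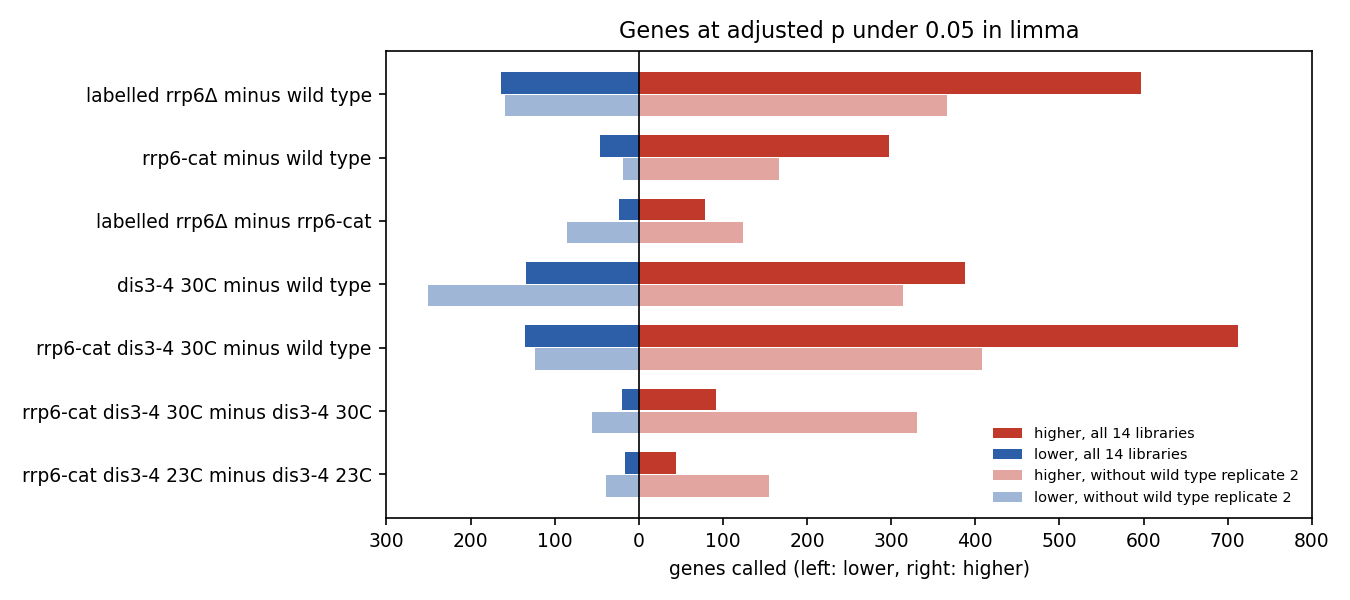
Genes called higher (right) or lower (left) by limma in 7 comparisons (x axis, number of genes), with dark bars for all 14 libraries and light bars without wild type replicate 2. The most, 847, were called in rrp6-cat dis3-4 at 30 °C against wild type, where 531 were called without that library; the 3 comparisons with 0 calls are not drawn.

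The libraries labelled rrp6Δ, in which the rrp6 gene itself was not low, were compared with wild type, and some mRNAs of meiosis were higher in them. All 11 measured mRNAs of the Mmi1 list, meiotic messages known to be removed in growing cells by the RNA-binding protein Mmi1 and the exosome, rose in the libraries labelled rrp6Δ. The count was also 11 adjusted over the list alone, and 11 with any 1 of the 4 libraries left out. Their median log2 fold change was 4.67 (camera adjusted p = 1.8e-16, adjusted p = 0.061 with an estimated correlation). The mRNA of spo5 (SPBC29A10.02, chromosome II), an RNA-binding protein of meiosis, rose from 2.47 ± 2.11 to 657 ± 43 FPKM (SD, n = 2), a log2 fold change of 7.71 (SE 0.40, adjusted p = 6.9e-07). The meiotic cohesin subunit rec8 (SPBC29A10.14) went from 2.99 ± 4.23 to 408 ± 80.5 FPKM (log2 7.26, SE 0.67, adjusted p = 2.9e-05). The transcription factor of meiosis mei4 (SPBC32H8.11) went from 3.99 ± 3.09 to 213 ± 6.31 FPKM (log2 5.58, SE 0.43, adjusted p = 6.7e-06). With either wild type library left out the fold changes moved: without wild type replicates 1 and 2 they were 8.37 and 7.05 for spo5, 8.66 and 5.86 for rec8, and 6.26 and 4.90 for mei4. The antisense gene pcf1 overlaps spo5, and cdk9 overlaps mei4 on the same strand, so reads of one can count for the other.

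Other meiotic groups rose in part in the libraries labelled rrp6Δ. In the list of middle meiosis and sporulation 7 of the 11 measured genes rose (9 adjusted over the list alone, 5 to 7 with 1 library left out). Among them was eng2, a glucanase, from 24.4 ± 7.33 to 575 ± 89.5 FPKM. The list's median was 2.45 (camera adjusted p = 6.1e-07, adjusted p = 0.13 with an estimated correlation). Of the 7 measured genes of meiotic recombination 5 rose, such as rec25, a linear element protein, and the meiotic cohesin subunit rec11 (median 2.81, camera adjusted p = 7.6e-05, adjusted p = 0.18 with an estimated correlation). In the list of mating and meiotic entry, 2 of 15 rose, rep1 with a log2 fold change of 3.76 (SE 0.26) and mei2 with 1.90 (SE 0.52), and camera made no call (adjusted p = 0.052). That count was 5 without wild type replicate 1 and 1 without any 1 of the other 3 libraries. The fold change of mei2 was 2.57 and 1.23 without wild type replicates 1 and 2. Its call was lost without wild type replicate 2 or either rrp6Δ library, with an adjusted p between 0.0047 and 0.18 over the 4 left-out libraries.

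**Figure D2:**
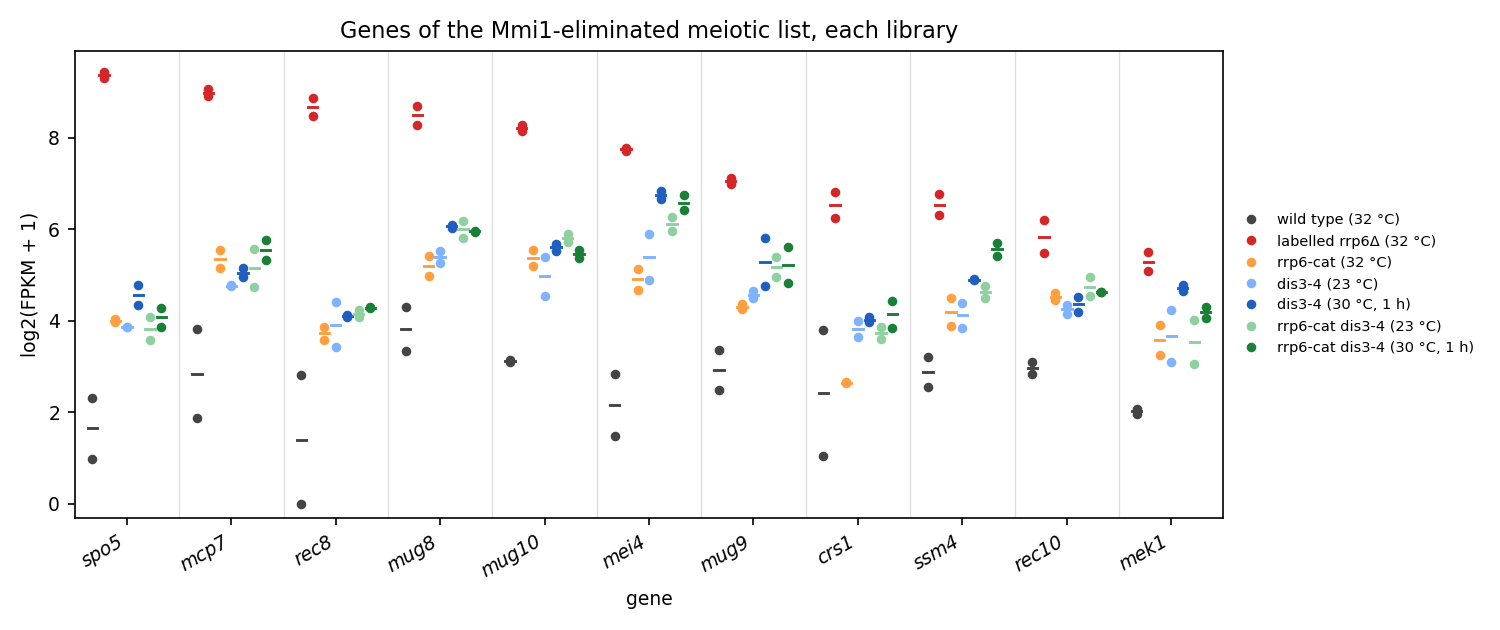
FPKM of genes of the Mmi1 list in each of the 14 libraries (y axis, log2(FPKM + 1)), by group, with points for libraries and a dash for the mean of the log2 values. The libraries labelled rrp6Δ lie highest: mean spo5 was 657 FPKM there, 2.47 in wild type and 13.4 to 22.8 in the other mutant groups.

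Some iron uptake genes and a metallothionein were also higher in the libraries labelled rrp6Δ. Of 11 iron acquisition genes 6 rose (7 adjusted over the list alone; 5 to 8 with 1 library left out; median 2.28, camera adjusted p = 3.4e-05, adjusted p = 0.2 with an estimated correlation). The ferric reductase frp1 rose from 6.35 ± 5.12 to 134 ± 12.4 FPKM (log2 4.40, SE 0.44, adjusted p = 4.8e-05; 5.17 and 3.62 without wild type replicates 1 and 2), and str3, a heme transporter, from 1.94 ± 1.43 to 88.2 ± 26.5 (log2 4.98, SE 0.67, adjusted p = 0.00047). The heme uptake gene shu1, a neighbour of str3 on chromosome I, was listed at 0 in both wild type libraries and at 104.5 and 121.9 FPKM in the libraries labelled rrp6Δ. Of the core environmental stress genes 4 of 13 rose, among them the metallothionein zym1, from 64.6 ± 5.02 to 610 ± 31.2 FPKM (log2 3.22, SE 0.45, adjusted p = 0.00063). That count was 2 without wild type replicate 2 and 1 without rrp6Δ replicate 2, and camera made no call on the list (adjusted p = 0.13).

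Noncoding RNA made up a large part of the rises in the libraries labelled rrp6Δ. The snoRNAs guide RNA modification and are not normally polyadenylated when mature. Of 39 measured, 25 rose (27 adjusted over the list alone; 18 to 26 with 1 library left out), with a median of 5.40 (camera adjusted p = 4.1e-13, adjusted p = 0.2 with an estimated correlation). snR5 rose from 20.2 ± 28.5 to 2070 ± 199 FPKM (log2 8.33, adjusted p = 0.001; 11.01 and 5.64 without wild type replicates 1 and 2). Of the 7 spliceosomal and related snRNAs 6 rose, snu3 from 1.12 ± 1.59 to 65.2 ± 29.5 FPKM (log2 5.12; 5.97 and 4.27 without wild type replicates 1 and 2; list median 3.42, camera adjusted p = 1.9e-05, adjusted p = 0.22 with an estimated correlation). Among 1397 long noncoding RNAs 299 rose and 31 fell (368 and 45 adjusted over the list alone; median 0.62, camera adjusted p = 1.6e-05, adjusted p = 0.61 with an estimated correlation). Quantile normalization gave 212 and 68. The rises ranged from 163 without rrp6Δ replicate 2 and 191 without rrp6Δ replicate 1 to 503 without wild type replicate 1, and the falls were 10 without rrp6Δ replicate 2 and 47 without wild type replicate 1. SPNCRNA.491 (chromosome III) had a mean of 0.007 FPKM in wild type and 3560 ± 375 in the libraries labelled rrp6Δ (log2 11.79, SE 0.45, adjusted p = 5.7e-08).

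Few lists were lower in the libraries labelled rrp6Δ. Camera placed the ribosomal proteins below other genes (median -0.16, adjusted p = 3e-06, adjusted p = 0.31 with an estimated correlation), with 1 rise and 4 falls among 133. The rise was that of rpl3002, from 130 ± 48 to 613 ± 217 FPKM. Without wild type replicate 1 there were 6 rises, and the falls were 2 and 1 without rrp6Δ replicates 1 and 2. The heat shock list had a median of -0.29 with 0 members called (camera adjusted p = 0.0024, adjusted p = 0.43 with an estimated correlation), and 3 fell without wild type replicate 2. The nitrogen starvation list had 0 called and a median of -0.47 (camera adjusted p = 0.041, adjusted p = 0.26 with an estimated correlation), a call lost without wild type replicate 2 or rrp6Δ replicate 1. In that list 5 genes fell without wild type replicate 1 and 1 rose without wild type replicate 2. None of the 6 largest falls named by the rule kept its call with each library left out in turn, and 5 of them lost it without 2 or 3 of the 4 libraries (SPNCRNA.1311, SPNCRNA.1307, SPMITTRNASER.02, meu20 and SPNCRNA.917). That of the uncharacterised SPBC460.04c (log2 -3.42, SE 0.66, adjusted p = 0.0052) was lost without rrp6Δ replicate 1 alone, at an adjusted p between 0.00083 and 0.052 over the left-out libraries. Its fold change was -4.34 and -2.51 without wild type replicates 1 and 2, and -2.81 and -4.03 without rrp6Δ replicates 1 and 2.

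In all, limma called 761 of 6083 genes between the libraries labelled rrp6Δ and wild type, 597 higher and 164 lower. The median of all tested genes was 0.23, and it was 0.03 with size factors and -0.14 with quantile normalization, under which the share of calls that were rises went from 78.4% to 62.9% and 49.6%. The count was 1618 without wild type replicate 1, 438 without rrp6Δ replicate 1 and 333 without rrp6Δ replicate 2. Without wild type replicate 2 it was 526, of which 429 were shared. Of 55 called genes named by the rule for this comparison, 28 kept their call with any 1 of the 4 libraries left out, among them spo5, rec8, mei4, mcp7, eng2, rep1, rec11, rec25, frp1, str3, shu1, zym1, snR5, snu3, SPNCRNA.491 and rpl3002.

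The gene rrp6 itself (SPAC1F3.01, chromosome I) was not low in the libraries labelled rrp6Δ. It stood at 179 and 128 FPKM in their replicates 1 and 2, at 95.4 and 43.2 in wild type and at 109 and 86.1 in rrp6-cat. Its log2 fold change of 1.22 against wild type (SE 0.36, adjusted p = 0.048) lost its call without wild type replicate 2 or either rrp6Δ library, with values from 0.66 to 1.79 and an adjusted p between 0.0029 and 0.27. Between the libraries labelled rrp6Δ and rrp6-cat it differed by 0.64 (SE 0.36, adjusted p = 0.55). The group is therefore named by its label throughout. Of 13 exosome subunit genes it was the 1 called, with 2 called without wild type replicate 1. The gene dis3 (SPBC26H8.10) had a log2 fold change of -0.20 against wild type in the libraries labelled rrp6Δ (SE 0.28, adjusted p = 0.72) and of 0.58 in dis3-4 at 30 °C (SE 0.28, adjusted p = 0.25).

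In the comparison of rrp6-cat with wild type, the largest rises were noncoding RNAs. Of 39 snoRNAs 20 rose (24 adjusted over the list alone; 11 without rrp6-cat replicate 2; median 4.37, camera adjusted p = 7.3e-16, adjusted p = 0.17 with an estimated correlation). The snoRNA sno16 went from under 0.001 FPKM in both wild type libraries to a mean of 394 ± 245 (log2 8.47, SE 0.46, adjusted p = 1.7e-06; 9.15 and 7.79 without rrp6-cat replicates 1 and 2), and snu3 from 1.12 ± 1.59 to 67.1 ± 0.303 (log2 5.24, SE 0.50, adjusted p = 0.00013; 6.09 and 4.39 without wild type replicates 1 and 2). All 7 snRNAs rose (5 to 7 with 1 library left out; median 3.93, camera adjusted p = 1.4e-10, adjusted p = 0.11 with an estimated correlation). Of 31 tRNAs 6 rose (12 adjusted over the list alone; median 2.28, camera adjusted p = 0.00039, adjusted p = 0.2 with an estimated correlation). That count was 3 without wild type replicate 2 or rrp6-cat replicate 1 and 1 without rrp6-cat replicate 2, and the camera call was lost without wild type replicate 1. Of long noncoding RNAs 173 rose and 8 fell (256 and 16 adjusted over the list alone; median 0.50, camera adjusted p = 1.6e-06, adjusted p = 0.53 with an estimated correlation). Rises were 404 without wild type replicate 1, 101 without wild type replicate 2 and 63 without rrp6-cat replicate 2, and falls were 34 without wild type replicate 1 and 4 without any 1 of the other 3 libraries.

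Some meiotic mRNAs rose in rrp6-cat as well. Of the Mmi1 list 7 of 11 rose (10 adjusted over the list alone; 4 without wild type replicate 2 and 2 without rrp6-cat replicate 2), with a median of 1.56 (camera adjusted p = 3.4e-08, adjusted p = 0.11 with an estimated correlation). The mRNA of mei4 rose to 29.3 ± 6.79 FPKM (log2 2.74, SE 0.43, adjusted p = 0.0029) and that of spo5 to 15 ± 0.484 (log2 2.35, SE 0.40, adjusted p = 0.0049). The fold changes were 3.41 and 2.06 for mei4 and 3.01 and 1.68 for spo5 without wild type replicates 1 and 2. The call of spo5 was lost without rrp6-cat replicate 2 (adjusted p between 0.00011 and 0.052). Of the recombination list 1 of 7 was called (5 adjusted over the list alone; 3 without wild type replicate 1 and 0 without rrp6-cat replicate 2; median 1.67, camera adjusted p = 0.003, adjusted p = 0.26 with an estimated correlation). The list of middle meiosis had 1 of 11 called, with a median of 0.15 that was -0.24 with quantile normalization (camera adjusted p = 0.96). Its count was 2 without wild type replicate 1 and 0 without any 1 of the other 3 libraries. The mRNA of red1, a subunit of the complex that hands meiotic RNA to the exosome, rose from 51.7 ± 18.1 to 195 ± 24.8 FPKM (log2 1.94, SE 0.26, adjusted p = 0.0011).

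Among the 6 largest falls in rrp6-cat were 2 overlapping genes. SPCC1259.08 went from 75.1 ± 20.1 to 4.27 ± 3.23 FPKM (log2 -3.98, SE 0.39, adjusted p = 0.00014). The gene pdx1 (SPCC1259.09c), a subunit of pyruvate dehydrogenase, overlaps it on the opposite strand, so reads of one can count for the other, and it went from 76.4 ± 17.5 to 9.12 ± 5.54 (log2 -3.03, SE 0.37, adjusted p = 0.00049). Without rrp6-cat replicates 1 and 2 the fold changes were -4.65 and -3.31, and -2.44 and -3.62. The ribosome biogenesis list had 2 of 20 called (3 adjusted over the list alone; 15 without wild type replicate 1, 1 without wild type replicate 2 or rrp6-cat replicate 1, 0 without rrp6-cat replicate 2). Its median was 0.48 (camera adjusted p = 0.016, adjusted p = 0.94 with an estimated correlation), and it was -0.16 without wild type replicate 2. The nitrogen starvation list had a median of -0.32 with 0 called, 2 lower adjusted over the list alone and 4 without wild type replicate 1 (camera adjusted p = 0.003, adjusted p = 0.17 with an estimated correlation; lost without wild type replicate 2). In all 343 genes were called, 297 higher and 46 lower. No call remained in a fit of the compared groups alone, which has few residual degrees of freedom. The median of all genes was 0.18, 0.03 with size factors and -0.11 with quantile normalization, under which rises made up 86.6%, 79.9% and 67.9% of calls. The count was 1253 without wild type replicate 1, 186 without wild type replicate 2 (165 shared) and 109 without rrp6-cat replicate 2. Of 42 called genes named by the rule, 20 kept their call with any 1 of the 4 libraries left out, among them mei4, red1, SPCC1259.08, pdx1, sno16 and snu3.

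Set directly against each other, the libraries labelled rrp6Δ held more RNA of the Mmi1 list and of some other meiotic and iron genes than rrp6-cat. Of the Mmi1 list 9 of 11 were higher (11 adjusted over the list alone; 5 without either rrp6Δ library), with a median of 2.84 (camera adjusted p = 1.2e-22, adjusted p = 0.046 with an estimated correlation). The mRNA of spo5 was 41.2-fold higher on the FPKM + 1 scale (log2 5.36, SE 0.40, adjusted p = 3.6e-05) and that of rec8 30.7-fold (log2 4.94, SE 0.67, adjusted p = 0.003). Of the middle meiosis list 6 of 11 were higher (10 adjusted over the list alone; 2 without rrp6Δ replicate 2 and 3 without rrp6-cat replicate 1; median 2.22, camera adjusted p = 1.1e-13, adjusted p = 0.061 with an estimated correlation), led by eng2 at 13.6-fold. Of the iron list 5 of 11 were higher (8 adjusted over the list alone; 3 without rrp6-cat replicate 1 and 1 without any 1 of the other 3; median 1.72, camera adjusted p = 7.3e-10, adjusted p = 0.11 with an estimated correlation), with shu1 36.9-fold higher (log2 5.21, SE 0.42, adjusted p = 4.9e-05). The recombination list had 2 of 7 called (5 adjusted over the list alone; 1 without rrp6Δ replicate 1 or rrp6-cat replicate 1, 0 without rrp6Δ replicate 2; median 1.53, camera adjusted p = 0.00031, adjusted p = 0.2 with an estimated correlation). The mating list had 1 of 15, rep1 (5 adjusted over the list alone; median 0.70, camera adjusted p = 0.001, adjusted p = 0.51 with an estimated correlation).

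Other lists were also compared between the libraries labelled rrp6Δ and those of rrp6-cat. No snRNA passed the test and 2 of 39 snoRNAs did, with 0 without either rrp6Δ library, 1 without rrp6-cat replicate 1 and 5 without rrp6-cat replicate 2 (median 0.86, camera adjusted p = 0.028, adjusted p = 0.89 with an estimated correlation; lost without rrp6Δ replicate 1 or rrp6-cat replicate 1). The heat shock list lay lower in the libraries labelled rrp6Δ (median -0.64, 0 called and 3 lower adjusted over the list alone; camera adjusted p = 3e-06, adjusted p = 0.22 with an estimated correlation), and so did the ribosomal proteins (median -0.31; 1 higher and 2 lower of 133, each lost without at least 1 compared library; camera adjusted p = 7.9e-13, adjusted p = 0.17 with an estimated correlation). In all 103 genes were called, 79 higher and 24 lower in the libraries labelled rrp6Δ. Rises made up 76.7% of calls, 58.2% with size factors and 56.3% with quantile normalization, which called 199. The count was 211 and 209 without wild type replicates 1 and 2, which only inform the shared spread, and 49, 23, 40 and 58 without rrp6Δ replicates 1 and 2 and rrp6-cat replicates 1 and 2. Of 28 called genes named by the rule, 10 kept their call with any 1 of those 4 left out: spo5, rec8, eng2, meu7, rep1, shu1, SPNCRNA.260, SPNCRNA.118, SPNCRNA.606 and SPNCRNA.1197.

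In dis3-4 at 30 °C, where the catalytic subunit of the exosome carries a temperature-sensitive allele, some meiotic mRNAs and some noncoding RNAs were higher than in wild type. Of the Mmi1 list 10 of 11 rose (11 adjusted over the list alone; 7 to 10 with 1 library left out; median 2.35, camera adjusted p = 1.2e-11, adjusted p = 0.098 with an estimated correlation). Its member mei4 was at 107 ± 9.24 FPKM against 3.99 ± 3.09 (log2 4.58, SE 0.43, adjusted p = 5.1e-05; 5.26 and 3.90 without wild type replicates 1 and 2) and spo5 at 22.8 ± 4.99 (log2 2.91, SE 0.40, adjusted p = 0.00087; 3.57 and 2.24 in the same order). Of the recombination list 4 of 7 rose (median 2.21, camera adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation; lost without wild type replicate 1), while 0 of 11 middle meiosis genes were called (median 0.11). Of 39 snoRNAs 16 rose (19 adjusted over the list alone; 11 to 17 with 1 library left out; median 2.41, camera adjusted p = 1.8e-09, adjusted p = 0.26 with an estimated correlation), among them snR10 from 38.8 ± 21.9 to 3310 ± 1290 FPKM (log2 6.44, SE 0.47, adjusted p = 1e-05; 7.03 and 5.85 without wild type replicates 1 and 2). Of long noncoding RNAs 253 rose and 15 fell (319 and 40 adjusted over the list alone; median 0.44, camera adjusted p = 2.4e-12, adjusted p = 0.27 with an estimated correlation). Rises were 389 without wild type replicate 1 and 119 without dis3-4 30 °C replicate 2, and falls were 28 and 37 without wild type replicates 1 and 2 and 8 without dis3-4 30 °C replicate 2. Of snRNAs 3 of 7 rose (5 adjusted over the list alone; 1 without dis3-4 30 °C replicate 2; median 2.32, camera adjusted p = 0.0015, adjusted p = 0.33 with an estimated correlation).

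A minority of the heat shock genes was called higher in dis3-4 at 30 °C than in wild type. Of 16 measured, 4 rose (6 adjusted over the list alone; median 0.69, camera adjusted p = 0.0023, adjusted p = 0.43 with an estimated correlation), such as wos2, an Hsp90 co-chaperone, from 639 ± 42.5 to 1370 ± 58.5 FPKM (log2 1.10, SE 0.20, adjusted p = 0.0051). The count was 8 without wild type replicate 1 and 1 without any 1 of the other 3 libraries. The glycerol phosphate dehydrogenase gpd1 fell from 400 ± 1.65 to 144 ± 43 FPKM (log2 -1.50, SE 0.21, adjusted p = 0.0011). The histone list had a median of -0.87 with 0 of 7 called (camera adjusted p = 0.04, adjusted p = 0.78 with an estimated correlation), a call lost with size factors, with quantile normalization and without wild type replicate 2 or dis3-4 30 °C replicate 2. In it 1 gene fell without wild type replicate 1 and 3 without dis3-4 30 °C replicate 1. In all 522 genes were called, 388 higher and 134 lower. The median of all genes was -0.03, and -0.14 with quantile normalization, under which rises made up 59.9% of calls in place of 74.3%. The count was 1020 without wild type replicate 1 and 198 without dis3-4 30 °C replicate 2. Of 43 called genes named by the rule, 23 kept their call with any 1 of the 4 libraries left out, among them mei4, spo5, snR10, wos2, gpd1 and rps1401.

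In rrp6-cat dis3-4 at 30 °C, some ribosome biogenesis factors rose beside some meiotic mRNAs and noncoding RNAs. Of 20 measured, 10 were higher than in wild type (11 adjusted over the list alone; median 1.07, camera adjusted p = 3.1e-05, adjusted p = 0.7 with an estimated correlation). Among them were imp4, a component of the machinery that processes small-subunit rRNA, from 45.5 ± 41 to 292 ± 0.41 FPKM (log2 3.01, SE 0.52, adjusted p = 0.0033; 4.07 and 1.96 without wild type replicates 1 and 2), gar2, the nucleolin of this yeast, and rrn3, an initiation factor of RNA polymerase I. The count was 20 without wild type replicate 1 and 3 without any 1 of the other 3 libraries. Of the Mmi1 list 10 of 11 rose (6 without double mutant 30 °C replicate 2; median 2.34, camera adjusted p = 1.6e-08, adjusted p = 0.11 with an estimated correlation), with mei4 at 95.1 ± 15.8 FPKM. Of the recombination list 4 of 7 rose (5 adjusted over the list alone; median 2.11, camera adjusted p = 0.0092, adjusted p = 0.31 with an estimated correlation), and 0 of 11 middle meiosis genes were called (median 0.42, and -0.49 with quantile normalization). All 7 snRNAs rose (4 without double mutant 30 °C replicate 1; median 3.02, camera adjusted p = 5.3e-06, adjusted p = 0.2 with an estimated correlation). So did 20 of 39 snoRNAs (24 adjusted over the list alone; 12 without double mutant 30 °C replicate 1; median 4.34, camera adjusted p = 2.7e-09, adjusted p = 0.26 with an estimated correlation). Of long noncoding RNAs 329 rose and 20 fell (393 and 24 adjusted over the list alone; median 0.70, camera adjusted p = 3.9e-07, adjusted p = 0.48 with an estimated correlation). Rises were 215 without wild type replicate 2 and 151 and 150 without double mutant 30 °C replicates 1 and 2, without which falls were 9 and 7.

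The phosphate gene tgp1, a glycerophosphodiester transporter next to a noncoding RNA, rose in the double mutant from 8.43 ± 1.59 to 83.1 ± 4.9 FPKM (log2 3.17, SE 0.33, adjusted p = 0.0001), on the same strand as the overlapping nc-tgp1. It was the 1 called gene of the 3 on the phosphate list (2 adjusted over the list alone; 3 without wild type replicate 1; median 0.85, camera adjusted p = 0.041, adjusted p = 0.35 with an estimated correlation), and the list's call was lost without wild type replicate 1 or 2 or double mutant 30 °C replicate 2. Of the iron list 4 of 11 rose (1 without double mutant 30 °C replicate 2; median 1.04, camera adjusted p = 0.031, adjusted p = 0.54 with an estimated correlation), a call lost with quantile normalization and without wild type replicate 1 or double mutant 30 °C replicate 2. In all 847 genes were called, 712 higher and 135 lower. The median of all genes was 0.24, 0.04 with size factors and -0.13 with quantile normalization, under which rises made up 84.1%, 65.4% and 52.8% of calls. The count was 1608 without wild type replicate 1, 531 without wild type replicate 2 (442 shared), and 306 and 283 without double mutant 30 °C replicates 1 and 2. Of 55 called genes named by the rule, 29 kept their call with any 1 of the 4 libraries left out, among them imp4, gar2, rrn3, mei4, tgp1, shu1, snu3 and aat1.

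Many genes were called in the same direction in several mutants. Between rrp6Δ and rrp6-cat, each against wild type, 216 genes were higher in both and 34 lower in both, where independent lists of these sizes would share 29.1 and 1.2, and 2 went opposite ways. Between rrp6Δ and the double mutant 397 were higher in both against 69.9, and between dis3-4 and the double mutant 315 against 45.4. These comparisons share the wild type libraries, which alone correlate effects across genes. The correlation across genes was 0.79 for rrp6Δ and rrp6-cat and 0.77 to 0.78 for the 3 pairs with the double mutant. For dis3-4 it was 0.70 with rrp6Δ and 0.71 with rrp6-cat. Unchanged groups simulated against the same wild type gave 0.71 (0.69 to 0.73), so those 2 pairs did not exceed it. Over the 6 pairs, 67.3% to 76.5% of genes had the same sign, against a simulated 75.2%. The covariance was 0.75 to 1.00 against a simulated 0.33 (0.30 to 0.35), while too few genes were called in the simulated groups (0.9 and 0.6 on average) to say how many calls unchanged groups would share. With the wild type libraries divided, 1 to each comparison of a pair, the correlation ran from 0.28 to 0.53 over the 6 pairs and both ways of dividing (simulated 0.00, -0.04 to 0.04). The share of genes with the same sign was then 42.1% to 60.8%. This division was chosen after the data were seen, and genes are not independent replicates. SPNCRNA.491, mei4, rep1 and rpl3002 were called higher in all 4 mutant groups compared with wild type, and each kept its call there with any 1 library left out.

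The shift from 23 to 30 °C asks what changes after 1 h at the higher temperature. Camera called several lists in dis3-4, among them that of heat shock genes, which had a median log2 fold change of 0.85 (camera adjusted p = 4.1e-13, adjusted p = 0.11 with an estimated correlation), with 0 of 16 genes called over all genes and 7 adjusted over the list alone. The Hsp70 gene ssa1 stood at 114 ± 21.7 FPKM at 23 °C and 278 ± 54.1 at 30 °C (log2 1.28, SE 0.29, adjusted p = 0.28 over all genes), sti1 at 204 ± 1.89 and 444 ± 54.8, and wos2 at 758 ± 3.84 and 1370 ± 58.5. These 3 were chosen after their values were seen. The Mmi1 list had a median of 0.68 (camera adjusted p = 4.5e-06, adjusted p = 0.17 with an estimated correlation) with 0 called either way of adjusting. Its member mei4, also chosen after its values were seen, stood at 43.7 ± 21.2 and 107 ± 9.24 FPKM. That was the largest change of the list (log2 1.35, SE 0.43), and the smallest was that of rec10 (log2 0.11, SE 0.31). No wild type library went through the shift, so the effect of heat alone was not measured. Limma called 0 genes in all (273 at an unadjusted p under 0.05), and 4 with size factors, 1 with no filter, 5 and 4 without wild type replicates 1 and 2, and 1 without dis3-4 23 °C replicate 1.

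In the double mutant camera made no call on the heat shock list over the same shift (adjusted p = 0.2): ssa1 stood at 319 ± 0.238 and 263 ± 27.7 FPKM, and sti1 at 282 ± 16.9 and 262 ± 9.84. The core environmental stress list had a median of -0.13 (camera adjusted p = 0.021, adjusted p = 0.68 with an estimated correlation; lost without double mutant 23 °C replicate 1 or 2 or 30 °C replicate 2) and the ribosomal proteins one of 0.13 (camera adjusted p = 0.0061, adjusted p = 0.67 with an estimated correlation; lost without double mutant 30 °C replicate 1, and turned in direction without double mutant 23 °C replicate 1). Limma called 0 genes (96 at an unadjusted p under 0.05), and 2 with no filter and 1 with no intensity trend. For the difference between the 2 strains' shifts, limma called 0 genes (163 at an unadjusted p under 0.05), and 3 with no filter and 1 with no intensity trend. Camera called the heat shock list lower in that difference (median -0.83, adjusted p = 1.5e-12, adjusted p = 0.11 with an estimated correlation), with ssa1 at -1.56 (SE 0.41) and sti1 at -1.22 (SE 0.33), the 2 genes called adjusted over the list alone.

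The double mutant was set against dis3-4 at the same temperature. By their labels the 2 strains differ in rrp6-cat, and whether they share a parent is not given. Genes of metal uptake were among those that differed. At 30 °C shu1 was listed at 0 in both dis3-4 libraries and at 30.38 and 22.49 FPKM in the double mutant, and at 23 °C it was listed at 0 in both and at 27.25 and 19.04. Of the iron list 3 of 11 were higher at 30 °C (6 adjusted over the list alone; 1 without dis3-4 replicate 2 or either double mutant library; median 1.33, camera adjusted p = 8.2e-05, adjusted p = 0.22 with an estimated correlation). At 23 °C it was 3 (4 adjusted over the list alone; 1 with any 1 library left out; median 0.63, camera adjusted p = 0.00034, adjusted p = 0.26 with an estimated correlation). Opposite to these, the zinc transporter zrt1 stood at 295 ± 22.3 FPKM in dis3-4 and 38.8 ± 8.88 in the double mutant at 23 °C (log2 -2.91, SE 0.30, adjusted p = 0.00096). The alcohol dehydrogenase adh4 (SPAC5H10.06c) stood at 724 ± 184 and 40.4 ± 15.7 FPKM at 30 °C (log2 -4.16, SE 0.36, adjusted p = 0.00024), and at 581 ± 30.7 and 31.1 ± 2.69 at 23 °C (log2 -4.18, SE 0.36, adjusted p = 0.00025). Wild type held 68.9 ± 25.9 FPKM of adh4 and 38.2 ± 14.5 of zrt1. SPAC977.05c, on chromosome I and with 2 near-identical matches elsewhere in the genome, had means of 685 and 1040 FPKM in dis3-4 at 30 and 23 °C, and 1.48 or less in every other group.

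**Figure D3:**
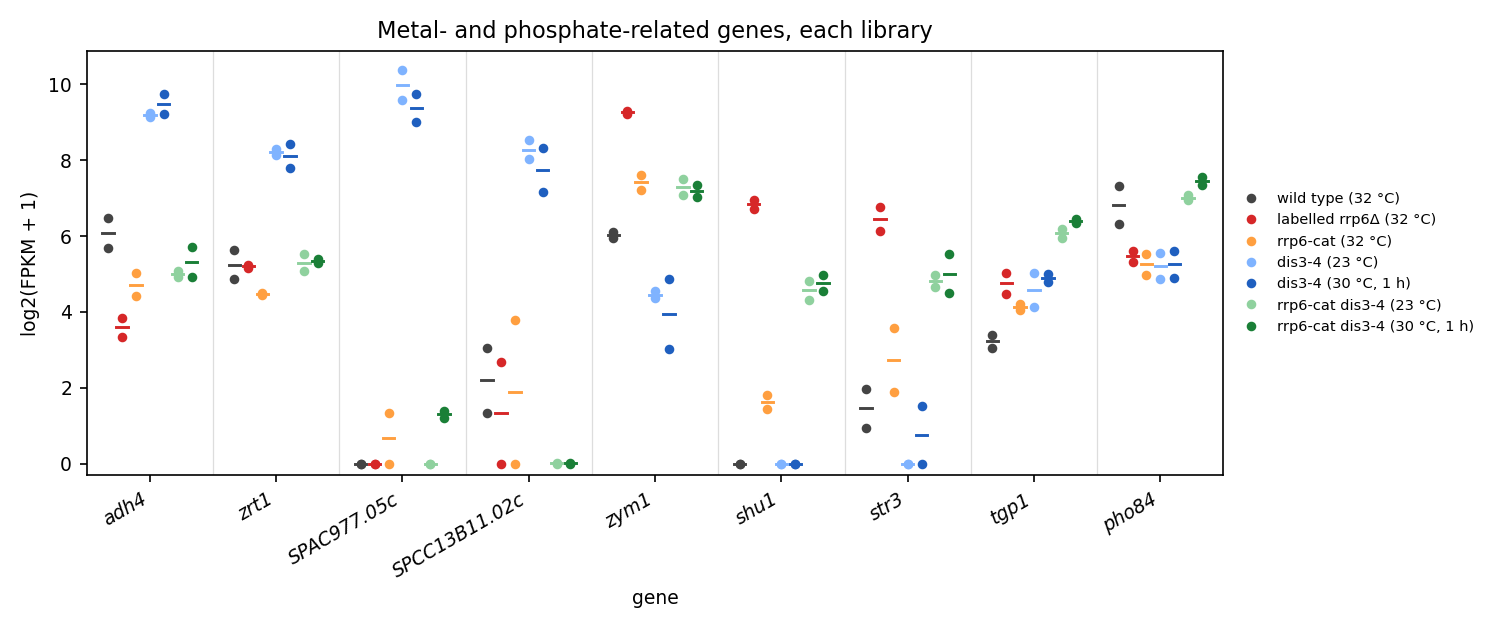
Genes of metal and phosphate uptake and others named with them in each of the 14 libraries (y axis, log2(FPKM + 1)), by group, with points for libraries and a dash for the mean of the log2 values. adh4 lies highest in the dis3-4 groups, at means of 581 and 724 FPKM, while shu1 is listed at 0 there.

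Some phosphate and stress genes were also higher in the double mutant than in dis3-4. Like tgp1, pho84 has an overlapping gene on the same strand, prt2, so reads of one can count for the other. At 30 °C the high-affinity phosphate transporter pho84 was at 175 ± 17.3 against 38.5 ± 13.6 FPKM, 4.59-fold higher on the FPKM + 1 scale (adjusted p = 0.015). It was called without dis3-4 30 °C replicate 2 and not without any 1 of the other 3 libraries, at an adjusted p between 0.042 and 0.19. Of the 3 phosphate genes 2 were called (1 without dis3-4 30 °C replicate 2, 0 without any 1 of the other 3; median 1.51, camera adjusted p = 0.0067, adjusted p = 0.24 with an estimated correlation; lost without dis3-4 30 °C replicate 1). At 23 °C 1 was called (3 adjusted over the list alone; 0 with any 1 library left out; median 1.49, camera adjusted p = 0.00029, adjusted p = 0.17 with an estimated correlation). Core stress genes had 3 of 13 higher at 30 °C (6 adjusted over the list alone; 1 without dis3-4 30 °C replicate 2 and 0 without either double mutant library; median 0.90, camera adjusted p = 0.00029, adjusted p = 0.37 with an estimated correlation). At 23 °C it was 2 (7 adjusted over the list alone; 0 with any 1 library left out; median 1.04, camera adjusted p = 4.6e-06, adjusted p = 0.26 with an estimated correlation). The metallothionein zym1 was at 146 ± 23.2 against 17.7 ± 15.1 FPKM at 30 °C (log2 3.24, SE 0.45, adjusted p = 0.0056; 4.18 and 2.31 without dis3-4 30 °C replicates 1 and 2; lost without either double mutant library, at an adjusted p between 0.00021 and 0.096).

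Camera placed heat shock genes lower in the double mutant than in dis3-4 at 30 °C (median -0.57, 1 of 16 called, wos2, and 3 adjusted over the list alone; 0 called with any 1 library left out; camera adjusted p = 8e-08, adjusted p = 0.19 with an estimated correlation). At 23 °C it made no call on that list (median 0.13, adjusted p = 0.62), and 1 of its genes was called, higher: ssa1 (2 adjusted over the list alone; log2 1.49, SE 0.29, adjusted p = 0.036), a call lost with any 1 compared library left out. At 30 °C camera placed ribosome biogenesis genes higher (median 0.90, 1 of 20 called, gar1, and 8 adjusted over the list alone; 0 called with any 1 library left out; camera adjusted p = 4.6e-06, adjusted p = 0.66 with an estimated correlation). The Mmi1 list had 0 of 11 called at 30 °C and a median of -0.06. In all limma called 112 genes at 30 °C, 92 higher and 20 lower, and 60 at 23 °C, 44 and 16. Of these 32 were higher and 9 lower at both temperatures, where independent lists would share 0.7 and 0.1. These comparisons share no library. The median of all genes was 0.23 and 0.10, and -0.01 and 0.00 with size factors, under which rises made up 69.7% of calls at 30 °C in place of 82.1% (67.9% with quantile normalization). At 30 °C the count was 386 without either wild type library, 23 without dis3-4 30 °C replicate 2, 9 and 11 without double mutant 30 °C replicates 1 and 2, and 52 to 72 without any 1 of the rrp6-cat or 23 °C libraries. At 23 °C it was 192 and 194 without wild type replicates 1 and 2, 10 to 20 without any 1 of the 4 libraries compared, and 26 without either double mutant 30 °C library. Of named called genes 6 of 27 at 30 °C kept their call with any 1 compared library left out (shu1, adh4, rps1401, SPAC750.01, SPAC977.05c, SPNCRNA.2002), and 4 of 22 at 23 °C (shu1, adh4, zrt1, SPAC977.05c).

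The 3′-ligated libraries cover one region of chromosome III, which in the deposited coordinates runs from 9506 to 10074. The files do not name the RNA. It is taken as a 5.8S rRNA and the spacer ITS2 that follows it in the precursor, since a 5.8S gene lies in that part of the ASM294v3 annotation with a 28S gene beside it toward lower positions. That build is not the one of the files, so this rests on the 2 builds agreeing there, which was not tested. The exosome and Rrp6 are known to trim the 3′ end of 5.8S rRNA. Coverage levelled off at 9842 to 9916 and 9926 to 9993 in all 3 libraries, with a maximum of 9014, so the amount of RNA cannot be read there. At 9830, 12 nt below the plateau's edge at 9842, coverage was 11 in wild type, 388 in rrp6Δ and 335 in rrp6-cat, ratios to wild type of 35.3 (95% interval 19.4 to 64.2) and 30.5 (16.7 to 55.5). As shares of the coverage summed outside the plateau these ratios are 2.79 and 3.24. At 9841, the position with the largest difference, it was 523, 1170 and 673, and as such shares the ratios are 0.177 and 0.137, so the direction turns there. The other 4 largest differences, at 9717, 9718, 9731 and 9736, lay farther from the plateau.

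Farther below the plateau coverage was also higher in both mutants. It stepped up at 9669, 173 nt below the edge, to 37 in wild type (26.1 to 51), 386 in rrp6Δ (348 to 426) and 295 in rrp6-cat (262 to 331), from 8, 94 and 90 at 9668. From 9669 to 9743 the median was 34, 512 and 328, ratios to wild type of 15.1 (10.6 to 21.3) and 9.65 (6.78 to 13.7). That window was set to 75 positions, the width of the plateau from 9842 to 9916. Coverage also dropped at its end. From 9743 to 9744 it went from 494 to 222 in rrp6Δ and from 334 to 138 in rrp6-cat. Wild type had 28 at 9743 and was not listed at 9744. The 17 positions from 9744 to 9760 were not listed in wild type, and coverage there was 128 to 222 in rrp6Δ and 97 to 159 in rrp6-cat. Both mutants lay above wild type, with 95% intervals that did not overlap, at 156 of the 156 positions from the step to the plateau that all 3 libraries list. With the 17 others taken as a wild type coverage of 0 it was 173 of 173. Neighbouring positions are covered in part by the same reads, so these counts are not of independent positions. Library totals are not known, and as a share of the coverage summed outside the plateau (5808, 73307 and 54511) both mutants lay above wild type at 20 of the 156 positions (37 of the 173) and below it at 5, with far ratios of 1.19 and 1.03.

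Ratios within a library do not depend on its total. The ratio of coverage at 9830 to that at 9841 was 0.021 in wild type (95% interval 0.012 to 0.038), 0.332 in rrp6Δ (0.296 to 0.372) and 0.498 in rrp6-cat (0.437 to 0.567). In rrp6-cat coverage between them was 287 at 9836, lower than at either, so not all reads at 9830 reach 9841. The far median as a share of itself plus the coverage at 9841 was 6.1% (Clopper-Pearson 95% interval 4.26 to 8.43), 30.4% (28.2 to 32.7) and 32.8% (29.9 to 35.8). These intervals do not include the spread between cultures, since each genotype has 1 library. The 5 largest values lay on the capped plateau, led by 9890 in wild type.

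**Figure D4:**
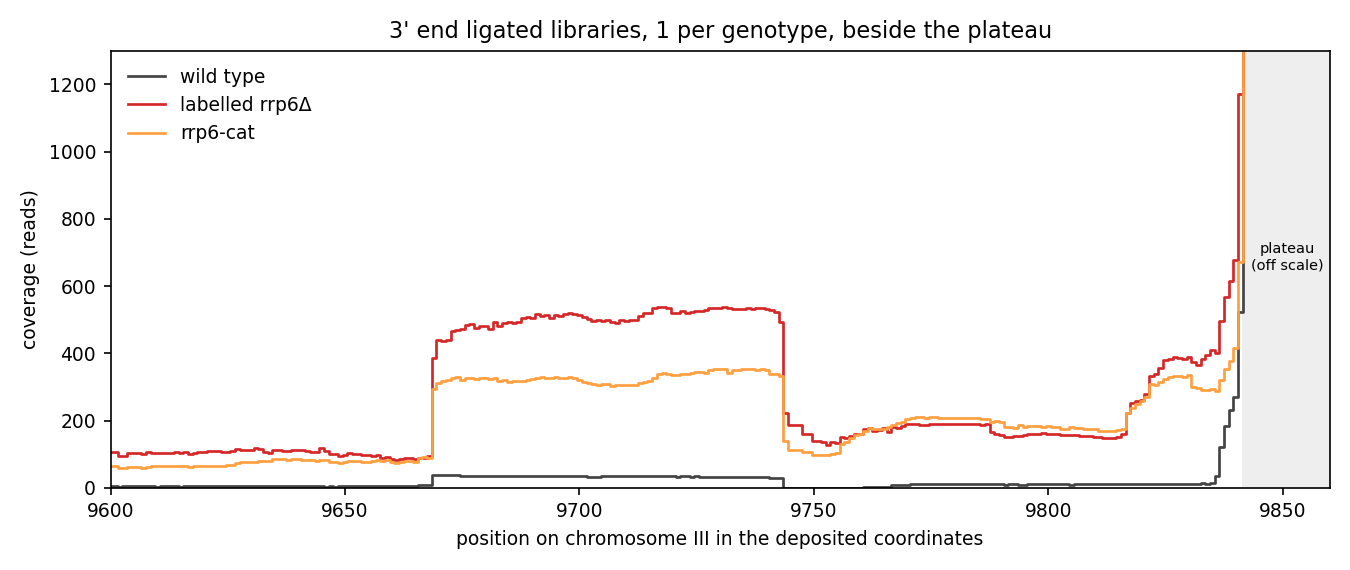
Coverage of the 3 libraries of 3′-ligated RNA (y axis, linear) along positions of chromosome III (x axis), with 1 line per genotype. Wild type stays at a median of 34 from 9669 to 9743, against 512 in rrp6Δ and 328 in rrp6-cat, and the plateau from 9842 is off the scale.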

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

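The tests of exchanged labels, of a part of the gene left in place, of a mislabelled mutant library and of the dis3-4 allele itself were chosen only after the result was seen. A direct test of whether the shift from 23 to 30 °C acted differently in rrp6-cat dis3-4 than in dis3-4 found 5 gene lists with a difference in camera and 0 single genes in limma (163 at an unadjusted p under 0.05; 3 with no filter and 1 with no intensity trend). The heat shock list differed by a median log2 of -0.83 (adjusted p = 1.5e-12, adjusted p = 0.11 with an estimated correlation), and the Mmi1 list by -0.41 (adjusted p = 0.0038, adjusted p = 0.31 with an estimated correlation). Ribosome biogenesis factors differed by 0.39 (adjusted p = 0.012, adjusted p = 0.94 with an estimated correlation), a call lost without replicate 1 of dis3-4 at 23 °C or at 30 °C. Ribosomal proteins differed by 0.24 (adjusted p = 0.00034, adjusted p = 0.48 with an estimated correlation), a call lost without double mutant 23 °C replicate 1 and turned in direction without dis3-4 30 °C replicate 1. Long noncoding RNAs had a median of 0.02 and a mean of -0.03, and camera placed them lower (adjusted p = 0.003, adjusted p = 0.83 with an estimated correlation), a call lost without replicate 2 of dis3-4 at 23 °C or at 30 °C.

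The gene rrp6 was at 179 and 128 FPKM in the 2 libraries labelled rrp6Δ, where a full deletion leaves no transcript. An exchange with rrp6-cat would leave rrp6 low there, and the lower of the rrp6-cat libraries held 124% of the wild type mean, which argues against it. Reads from a similar sequence were argued against by 0 other matches in the reference of at least 100 bases at 90% identity. A deletion that left part of the gene may explain the reads, and it cannot be told apart from an intact gene, since the files give 1 value per gene, 185% of the wild type mean in the lower library. A strain other than the one named in the label also stays open, and no biological explanation was tested.

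Wild type replicate 2 lay apart from replicate 1, and it decides part of the calls against wild type. Lower depth would show in weakly expressed genes only, but among 2170 genes of at least 50 FPKM the spread between the wild type replicates (SD 0.960) was 1.39 times the largest of the other 6 pairs (0.693), which argues against depth as the whole cause. Loss of signal along long transcripts is argued against by a rank correlation of -0.17 with gene length, inside the range of the other pairs (-0.32 to 0.13). A mutant library mislabelled as wild type is unlikely, since the mean log2 level of the Mmi1 list was 1.95 there and 3.65 in the lowest mutant library, a gap of 1.70 against 0.45 between the wild type replicates. A difference in growth between the wild type cultures may remain, and no biological explanation was tested.

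A set of 9 genes was lower in rrp6-cat dis3-4 than in dis3-4 at both temperatures: adh4, zrt1, ubi4, the4, SPAC977.05c, SPCC13B11.02c, SPAC8E11.10, SPBC23G7.14 and SPNCRNA.1305. Of these, limma called 6 higher in dis3-4 at 30 °C than in wild type, and not SPAC8E11.10, the4 or SPNCRNA.1305 (109 FPKM against 120 in wild type). The call of SPBC23G7.14 was lost without wild type replicate 2 or either dis3-4 30 °C library and that of SPCC13B11.02c without dis3-4 30 °C replicate 1, while SPAC8E11.10 was called without wild type replicate 1 and the4 without wild type replicate 2. Reads shared between near-identical copies are argued against for the set, as 1 of the 9, SPAC977.05c, has another match of at least 200 bases at 95% identity. Low zinc, which raises adh4 and zrt1, could not be tested with adh1, which reached 1 FPKM in 0 libraries, so it may still account for both and cannot be told apart from other differences between the strains. Another of the 9, SPCC13B11.02c, overlaps adh1AS on the same strand, so reads of one can count for the other. SPCC13B11.02c had means of 313 and 232 FPKM in dis3-4 at 23 and 30 °C. Its means were 4.41 in wild type, and 0.00673 and 0.00743 in the double mutant at 23 and 30 °C. Whether it follows zinc was not tested. The dis3-4 allele itself could not be tested with these genes: 9 of the 9 lay over 1 log2 unit lower in the double mutant, which carries the same allele, but they were chosen for being lower there. In rrp6-cat without dis3-4, SPNCRNA.1305 was called lower than in wild type (log2 -2.51, adjusted p = 0.00071, and -3.04 to -1.99 with 1 library left out, called each time), so its low level does not need dis3-4. There adh4 was called lower as well (log2 -1.36, adjusted p = 0.047; lost without wild type replicate 2 or either rrp6-cat library), and zrt1 and the4 were called lower without wild type replicate 1 alone. For the other genes an effect of rrp6-cat stays open, as does a variant elsewhere in the dis3-4 strain, which was not tested. Of the 9, the4 overlaps dis3, the gene of the dis3-4 allele, on the opposite strand. SPBC23G7.14 overlaps rpp202 on the opposite strand. Reads of one can count for the other where strand was not used, and whether the level of the4 follows from its place at dis3 was not tested.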

How the results depend on the processing

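The alternatives reported here were chosen before the data were examined, except the count over listed positions of the 3′ coverage, which was chosen after. An arm left with 1 library is assumed to vary like the other groups. With each of the 14 libraries left out in turn, counts of called genes ranged from 333 to 1618 for rrp6Δ against wild type (761 with all libraries), 109 to 1253 for rrp6-cat against wild type (343), 23 to 211 for rrp6Δ against rrp6-cat (103), 198 to 1020 for dis3-4 at 30 °C against wild type (522), and 283 to 1608 for the double mutant at 30 °C against wild type (847). They ranged from 0 to 5 for the shift in dis3-4 (0), 9 to 386 for the double mutant against dis3-4 at 30 °C (112) and 10 to 194 at 23 °C (60), and were 0 throughout for the shift in the double mutant and for the difference between shifts. The highest counts against wild type came without wild type replicate 1 and the lowest without a mutant library. The spread between replicates, taken across all groups, falls when a library of wild type, the most variable group (mean square 0.663, and 0.166 to 0.334 in the other groups), is left out. It falls alike without either wild type library. Without wild type replicate 2, though, fewer genes were called for rrp6Δ, rrp6-cat and the double mutant against wild type. The lower spread alone therefore does not account for the highest counts.

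Fitting only the groups compared leaves 2 residual degrees of freedom for a pair of groups, and the counts fell to 73, 0, 15, 26 and 71 in the order of the first 5 comparisons above (for rrp6-cat against wild type, limma gave 549 genes at an unadjusted p under 0.05), and to 15 and 8 for the double mutant against dis3-4 at 30 and 23 °C; of 272 called pairs of named gene and comparison, 61 kept their call. For the double mutant against dis3-4 at 23 °C the count was 93 with size factors, 102 with quantile normalization, 91 with a pseudocount of 5 and 39 with no intensity trend, and quantile normalization gave 199 for rrp6Δ against rrp6-cat. Against 0 called genes, the shift in dis3-4 gave 4 with size factors and 1 with no filter, the shift in the double mutant 2 with no filter and 1 with no intensity trend, and the difference between shifts 3 with no filter and 1 with no intensity trend. For these the cause was not tested. Among the list tests, camera's direction turned 4 times. The median for ribosome biogenesis in rrp6-cat ran from -0.16 without wild type replicate 2 to 1.09 without wild type replicate 1. That for ribosomal proteins ran from -0.22 to -0.01 in the shift of dis3-4 and turned without dis3-4 30 °C replicate 1, from 0.07 to 0.18 in the shift of the double mutant and turned without double mutant 23 °C replicate 1, and from 0.15 to 0.35 in the difference between shifts and turned without dis3-4 30 °C replicate 1. The cause was not tested. The number of list calls ran from 61 to 78 over the alternatives against 72, and the further requirement of 1 log2 unit has no meaning for them. No called named gene changed sign under any alternative run. With replicate number as a block the counts were 887, 423, 134, 654 and 993 in the order of the first 5 comparisons above. They were 0 for both shifts and their difference, and 154 and 90 for the double mutant against dis3-4. Same-numbered libraries of 21 pairs of groups deviated together with a median correlation of 0.03 across genes (-0.15 to 0.31). The 3 highest were those among the groups at 32 °C (0.19 for wild type with rrp6Δ, 0.27 for wild type with rrp6-cat and 0.31 for rrp6Δ with rrp6-cat), so same-numbered libraries may share something there, where the block raised the counts to 887, 423 and 134. The labels pair no libraries, and the numbers were not read as pairs.

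Along the 3′ coverage both mutants lay above wild type at 173 of 173 positions with a minimum of 10, of 100 or none, with positions not listed taken as 0, and at 156 of 156 that all 3 libraries list. Positions that share reads are not independent of each other. The count of positions with both mutants above wild type was 98 in a narrower and 324 in a wider window (81 and 307 over listed positions), which hold different numbers of positions. It was 37 as a share of summed coverage (20 over listed positions), which divides each library by a sum in which the mutants are themselves higher. What depth limits was not varied: with 2 libraries per group as they are, simulated changes of 1 log2 unit were found in 16.8% of genes for rrp6Δ against wild type. That simulation gave wild type the same spread as the other groups.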

Other observations

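The tests of exchanged labels, of a part of the gene left in place, of a mislabelled mutant library and of the dis3-4 allele itself, reported with the results above, are those chosen only after the result was seen, and none is reported here. A minority of the factors that recognise RNA for the exosome was called higher in some mutants. In the libraries labelled rrp6Δ 4 of 14 adaptor genes rose (4 adjusted over the list alone; camera adjusted p = 0.34), among them red1 from 51.7 ± 18.1 to 145 ± 15.2 FPKM (SD, n = 2; log2 1.50, SE 0.26, adjusted p = 0.0031) and mmi1 from 11.5 ± 6.78 to 31.5 ± 5.49 (log2 1.49, SE 0.39, adjusted p = 0.027; 0.90 without wild type replicate 2). The count was 2 without wild type replicate 2 or rrp6Δ replicate 2 and 1 without rrp6Δ replicate 1, and red1 kept its call. In the double mutant at 30 °C 4 of 14 rose as well (camera adjusted p = 0.29), with mmi1 at 42.8 ± 6.08 FPKM; the count was 2 without wild type replicate 2, and 1 and 0 without double mutant 30 °C replicates 1 and 2. In cytoplasmic decay 2 of 19 genes rose in the libraries labelled rrp6Δ, the deadenylase pop2 (log2 1.55, SE 0.30) and dcp1 (1.05, SE 0.22), and lsm1 fell by 1.37 (SE 0.37; by 1.99 and 0.74 without rrp6Δ replicates 1 and 2); the rises were 4 without wild type replicate 1 and 0 without rrp6Δ replicate 1, and the fall was lost without wild type replicate 2 or rrp6Δ replicate 2. Of the tRNAs 7 of 31 rose and 1 fell there (8 and 1 adjusted over the list alone; camera adjusted p = 0.11), SPATRNATYR.01 from a listed 0 in both wild type libraries to 16.71 and 56.0 FPKM; the rises were 4 without wild type replicate 2 and 1 without rrp6Δ replicate 1, and the fall was lost without any 1 of wild type replicate 2 and the rrp6Δ libraries. Of the rRNA features 2 of 17 rose (0 without wild type replicate 2, 1 without rrp6Δ replicate 1). In the thiamine, histone and mitochondrial lists limma called 0 of 5, 0 of 7 and 0 of 10 (camera adjusted p = 0.98, 0.2 and 0.74), where leaving out wild type replicate 1 gave 1 in each.

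Phosphate genes went apart from each other in the libraries labelled rrp6Δ and in dis3-4. On the same strand tgp1 overlaps nc-tgp1, pho84 overlaps prt2 and pho1 overlaps nc-pho1, so reads of one can count for the other. In the libraries labelled rrp6Δ tgp1 rose from 8.43 ± 1.59 to 26.5 ± 7.55 FPKM (log2 1.53, SE 0.33, adjusted p = 0.011; lost without rrp6Δ replicate 1) while pho84 fell from 118 ± 55.9 to 43.5 ± 6.31 (log2 -1.34, SE 0.37, adjusted p = 0.035; lost without wild type replicate 1 or either rrp6Δ library). In dis3-4 at 30 °C tgp1 was at 28.6 ± 2.98 FPKM and pho84 at 38.5 ± 13.6 (log2 1.66 and -1.55), with the tgp1 call lost without either dis3-4 30 °C library and the pho84 call lost without wild type replicate 1 or dis3-4 30 °C replicate 1. In rrp6-cat pho84 was called lower (log2 -1.56, SE 0.37, adjusted p = 0.031; lost without wild type replicate 1 or either rrp6-cat library) and tgp1 was not called (log2 0.91, SE 0.33, adjusted p = 0.16), while 2 of the 3 genes fell without wild type replicate 2. The acid phosphatase pho1 was higher in the libraries labelled rrp6Δ than in rrp6-cat, at 213 ± 14.7 and 78.5 ± 0.698 FPKM (log2 1.43, SE 0.27, adjusted p = 0.018), a call lost without any 1 of the 4 libraries, and the list's camera call there (median 0.62, adjusted p = 0.041, adjusted p = 0.35 with an estimated correlation) was lost without rrp6Δ replicate 1 or rrp6-cat replicate 2. Camera also called the phosphate list in the shift of dis3-4 (median 0.31, adjusted p = 0.025, adjusted p = 0.31 with an estimated correlation; lost without replicate 2 at either temperature) and in that of the double mutant (median 0.44, adjusted p = 0.036, adjusted p = 0.34 with an estimated correlation; lost without any 1 of the 4 libraries).

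Some snRNAs and 1 nitrogen gene were also called higher in the double mutant than in dis3-4. At 23 °C 3 of 7 snRNAs were higher (median 1.22, camera adjusted p = 6.7e-05, adjusted p = 0.24 with an estimated correlation; 2 without dis3-4 23 °C replicate 1 and 0 without any 1 of the other 3), with snu3 at 49.7 ± 2.79 against 2.94 ± 0.434 FPKM, and at 30 °C 2 were (median 1.55, camera adjusted p = 0.0041, adjusted p = 0.39 with an estimated correlation; 0 with any 1 library left out, and the camera call lost without dis3-4 30 °C replicate 1). The ammonium transporter amt1 was the 1 of 10 nitrogen genes called at each temperature, at 41.5 ± 5.22 against 7.07 ± 1.21 FPKM at 30 °C (log2 2.40, SE 0.41, adjusted p = 0.015) and 38.7 ± 3.86 against 9.47 ± 3.1 at 23 °C (log2 1.95, SE 0.41, adjusted p = 0.047), each lost with any 1 compared library left out. The nitrogen list had medians of 1.05 and 0.82 (camera adjusted p = 0.0069 and 0.017, adjusted p = 0.17 and 0.2 with an estimated correlation), with the call at 30 °C lost without dis3-4 30 °C replicate 1 and that at 23 °C lost with either other scaling and without dis3-4 23 °C replicate 1. At 23 °C camera further called ribosomal proteins (median -0.16, adjusted p = 2.9e-07, adjusted p = 0.26 with an estimated correlation; lost with quantile normalization), histones (0.76, adjusted p = 0.016, adjusted p = 0.7 with an estimated correlation; lost without dis3-4 23 °C replicate 1), ribosome biogenesis factors (0.36, adjusted p = 0.032, adjusted p = 0.94 with an estimated correlation; kept without dis3-4 23 °C replicate 1 and lost without any 1 of the other 3) and tRNAs (1.27, adjusted p = 0.028, adjusted p = 0.4 with an estimated correlation; lost without dis3-4 23 °C replicate 1 or double mutant 23 °C replicate 2).

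The meiotic noncoding RNA sme2, which holds Mmi1 away from its targets in meiosis, was at 2530 ± 1860 FPKM in the libraries labelled rrp6Δ and 119 ± 130 in rrp6-cat (log2 4.81, SE 0.95, adjusted p = 0.024; 3.35 to 6.26 with 1 library left out, without rrp6-cat replicates 1 and 2), a call lost without rrp6-cat replicate 1 or either rrp6Δ library. In the shift of dis3-4 camera placed ribosomal proteins lower (median -0.11, adjusted p = 0.027, adjusted p = 0.77 with an estimated correlation; lost without dis3-4 23 °C replicate 1, and turned without dis3-4 30 °C replicate 1) and long noncoding RNAs higher (median 0.05, adjusted p = 0.001, adjusted p = 0.77 with an estimated correlation; lost without replicate 2 at either temperature). Camera placed ribosome biogenesis factors lower in the libraries labelled rrp6Δ than in rrp6-cat (median -0.16, adjusted p = 0.032, adjusted p = 0.94 with an estimated correlation). That call was lost without rrp6Δ replicate 2 or rrp6-cat replicate 2. Of 199 named genes 194 were found in the reference, and 135 of those overlap another gene, 26 on the same strand and 128 on the opposite strand, so their values can include reads of another gene where strand was not used.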
